A study of Schizosaccharomyces pombe with 5 samples.

How the data were processed

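Fission yeast DNA was hybridised to 5 Agilent tiling arrays with 2 colours each. Per the labels, Cy5 carried DNA immunoprecipitated with FLAG-tagged Rec12, and Cy3 carried the whole-cell input of the same culture. The labels put 1 array in the wild type (WT), 1 in rec27Δ, 1 in rec10Δ and 2 in rec8Δ. No dye swap was given, so dye bias was not measured. By the labels' protocols, cells were starved of nitrogen for about 18 h and collected 5 h after nitrogen was returned at 34 °C. Fragments were about 500 to 1000 bp long, no crosslinker was added, and the material was PCR-amplified while the dyes were incorporated.

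The deposited scanner output was made with Agilent Feature Extraction 10.1.1.1, per the file headers. The intensity columns hold, per the file headers, the raw median brightness of each spot and its local background, and processed signals that the software had background-subtracted and scaled with a linear dye factor. The deposited log10 ratio column equalled the log10 of processed Cy5 over processed Cy3. A second deposited table of the same arrays held that log10 ratio minus each array's median (its column medians were 0), a scale found by setting it against the scanner values. The array design gives each probe a chromosome position; its genome build is not given in the sources used here.

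Each array had 45220 spots, of which 2513 were control spots, 66 were mitochondrial probes and 42641 were probes on the nuclear chromosomes (18958, 15339 and 8344 on chromosomes I, II and III) at a median spacing of 265 bp. The value of a probe was the log2 of processed IP over processed input, minus the array's median over nuclear probes. A value of 0 is therefore the array's own median, and an even change over the whole genome cannot be seen. Features the software marked as outliers were left out: 582 on WT, 139 on rec27Δ, 0 and 92 on the rec8Δ arrays and 10 on rec10Δ. The median raw IP brightness was 8387, 28055, 35377, 14127 and 31759 in that order, over local backgrounds of 122 to 131. The median raw input brightness was 19087, 13299, 17735, 26488.5 and 16833, over backgrounds of 27 to 31.5. The number of arrays limits the precision, and the labels do not say whether the rec8Δ arrays came from separate cultures, so their spread may be technical.

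Positions are those of the array design. Gene names came from the ASM294v3 annotation. Its long non-coding RNA genes were left out throughout, so all genes, stretches between genes and gaps between genes refer to the remaining genes. To check the positions, the GC content of that sequence under each probe was set against the probe's input signal at a range of shifts, in 51 windows of 250 kb. The correlation peaked within 200 bp of the stated positions in 43 windows. In the other 8, all on chromosome I from 3750001 onward, it peaked near a shift of 6210 bp. Probes there (6063) were analysed by position and not annotated, and 36578 probes were annotated. The hotspots between positions 3981925 and 5269849 of chromosome I therefore carry no gene name.

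Hotspots were called on smoothed values (the mean of probes within 500 bp, at least 2 probes) as runs of at least 3 consecutive probes at 2-fold or more over the array median, with runs within 1 kb merged. The level of a hotspot, 1-kb bin (at least 2 probes) or gene (from 500 bp upstream to 500 bp downstream) was the mean of its probes. Each was tested with limma 3.58.1 in R 4.3.3 on all 5 arrays, with a mean per genotype, eBayes, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. The residual spread had 1 degree of freedom and came from the rec8Δ arrays alone, so the lone WT, rec27Δ and rec10Δ arrays were assumed to vary as those do. Neighbouring hotspots were compared with a permutation test of 100000 draws within chromosomes, one-sided for a positive correlation. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

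The steps were tested on simulated data. With noise of SD 0.311 and 200 of 12011 bins shifted, the rec8Δ against WT fit recovered 0 bins shifted by −1 on the log2 scale, 194 shifted by −2 (with 11 false calls) and 200 shifted by −4 (with 7 false calls). All bins and arrays were given the same noise, without a difference in slide or IP content, so these counts need not hold for the real arrays. The hotspot rule recovered 100 of 100 planted regions and called 0 others. The regions were planted at a log2 of 3 in noise of SD 0.3, so regions near the 2-fold threshold were not tested. The neighbour statistic was −0.01 with no relation planted and 0.50 with a planted correlation of 0.5.

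The tests, the main alternatives, the gene lists and the rule for named features were chosen before the data were examined. The rule named the 10 strongest WT hotspots and, per mutant, the 10 largest called decreases, the 10 highest differences from WT (the 3 highest are given by name), the 5 strongest own regions outside WT hotspots, the largest called rec27Δ against rec8Δ differences, the genes rec8, rec10, rec27, rec12 and ade6, and the members of 14 gene lists. The lists covered break formation and chromosome axis, strand exchange and repair, meiosis regulators, pheromone and mating, nitrogen starvation, stress response, glycolysis, histones, ribosomal proteins, the wtf family, Tf2 retrotransposons, tRNA genes, cell surface and membrane transport. A list's median was set against 10000 random lists of the same size, drawn from all genes for the WT level and from genes of like mean ratio for a difference. Alternatives were normexp background correction with an offset of 50 on the median spot signals (the files gave no mean spot signal), loess, quantile normalisation, centring on the mode, leaving out dim probes, a slide block, other hotspot definitions, the deposited log10 table, a trend in eBayes, leaving out each rec8Δ array, 2-kb bins, gene spans without flanks and 50-kb subtelomeres. A common input and further scalings of the gene lists were added after seeing the data. No control IP without the tag was analysed here.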

Results

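DNA covalently bound to Rec12, the fission yeast orthologue of Spo11 that makes meiotic double-strand breaks, was measured along the genome 5 h into meiosis. Because Rec12 stays attached to the broken ends, enrichment of its DNA over whole-cell input marks where breaks were made. The 5 arrays comprised 1 of WT, 1 labelled rec27Δ, 2 labelled rec8Δ and 1 labelled rec10Δ. Rec8 is the meiotic subunit of cohesin, and Rec10 and Rec27 are components of the linear elements, the axis structures of fission yeast meiotic chromosomes. All values are log2 ratios of IP to input relative to the array's own median, read from 42641 nuclear probes, and errors given with ± are SD over the 2 rec8Δ-labelled arrays. WT, the rec27Δ-labelled array and the rec10Δ-labelled array had no replicate. WT and rec8Δ-labelled replicate 2 shared slide 1, and the other 3 arrays shared slide 2. The probe values spread most on WT (SD 1.83), less on rec8Δ-labelled replicate 2 (0.635), and least on rec8Δ-labelled replicate 1 (0.298), the rec27Δ-labelled array (0.309) and the rec10Δ-labelled array (0.313).

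The deleted genes were read first, to check the labels. In the input channel each deletion was found on the array that carried its name. Taking the mean input of the same probes on the arrays of the other strains as 100%, rec8 (chromosome II, 2568938 to 2570993, 7 probes) had 3.94% and 0.141% of its input signal left on rec8Δ-labelled replicates 1 and 2. The rec27 gene (chromosome II, 757399 to 758042, 2 probes) had 4.82% left on the rec27Δ-labelled array. On the rec10Δ-labelled array the longest run of probes with low input (chromosome I, 4295394 to 4297467, 8 probes) had 3.15% left, and the annotated start of rec10 in ASM294v3 lies 5973 bp from its start, close to the 6210 bp by which array positions beyond 3750000 on chromosome I differ from that build. On slide 2 the IP channel did not follow. On the same scale, IP signal at the deleted gene was 81.5% on the rec10Δ-labelled array, 70.9% on the rec27Δ-labelled array, 33.5% on rec8Δ-labelled replicate 1 and 1.47% on rec8Δ-labelled replicate 2. Conversely, rec8 was at 55.4% and 43.7% in the IP of the rec27Δ-labelled array and the rec10Δ-labelled array, whose inputs held 88.5% and 95.8% of it. In the IP of WT, which carries rec8, it was at 72.6%. The IP of the 3 arrays of slide 2 therefore goes against their labels, and these arrays are called rec8Δ-labelled, rec27Δ-labelled and rec10Δ-labelled here. Because rec8Δ-labelled replicate 1 is among them, the spread of the rec8Δ-labelled pair includes a difference in slide and in IP content. That spread gives the SD of rec8Δ-labelled values and underlies every limma test. Ratios at the deleted genes themselves have almost no input below them and do not measure breaks.

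**Figure D1:**
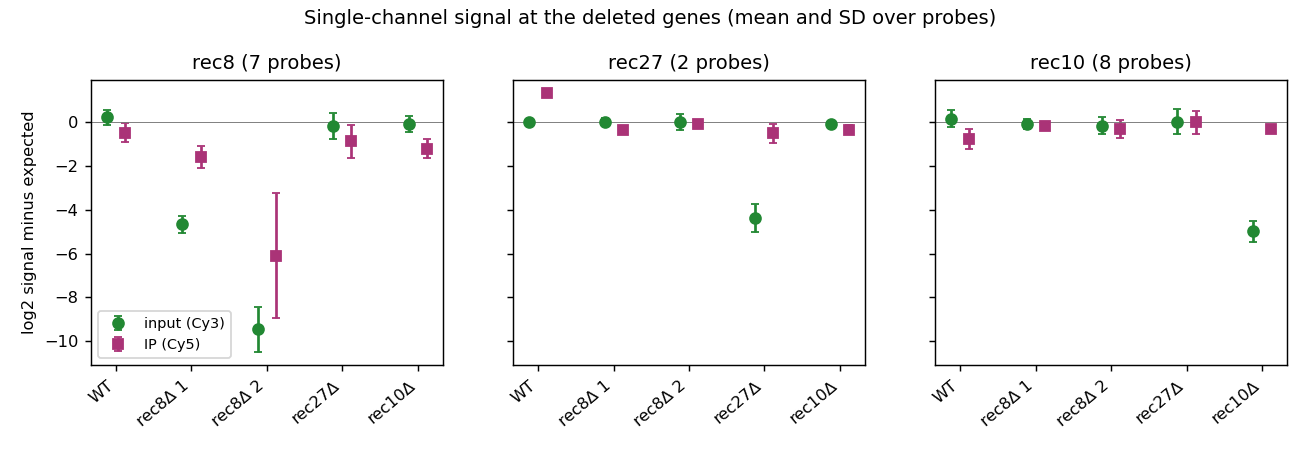
Signal of each channel at rec8 (7 probes), rec27 (2 probes) and rec10 (8 probes) on the 5 arrays, as log2 signal minus the level expected from the inputs of the other strains; circles are input (Cy3), squares are IP (Cy5), and bars are SD over probes. Input falls by more than 4 log2 units where a gene is deleted, whereas the IP of the slide 2 arrays stays within 2 units of the expected level.

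In WT, Rec12-bound DNA was concentrated in 714 hotspots with a median length of 3049 bp, which together covered 3284.48 kb and held 28.6% of the probes. There were 299 on chromosome I, 250 on II and 165 on III, with a median level of 2.01 and a maximum of 5.14. Among the 10 strongest were those between pcs2 and hsr1 (chromosome I, 1949088 to 1961063) at 5.12, between wis1, the kinase that activates the Sty1 stress MAP kinase, and its neighbour (chromosome II, 1145310 to 1152683) at 4.71, and between cyc3 and ste11, which encodes the transcription factor that starts sexual differentiation (chromosome II, 3975572 to 3988032), at 4.70. Those between rps1801 and the MADS-box gene mbx2 (chromosome II, 3620343 to 3635480), beside uba3 (chromosome I, 449600 to 465836) and beside txc1 (chromosome II, 959992 to 969048) had levels of 4.69, 4.65 and 4.59. The remaining 4 lay on the unannotated part of chromosome I, at 3981925 to 3989886 (5.14), 4429007 to 4434839 (4.97), 4778370 to 4786885 (4.83) and 4169777 to 4180123 (4.66). Of the 625 hotspots with annotation, 424 (67.8%) had their summit between genes, where 21.6% of annotated probes lay (Fisher's exact test, two-sided, p = 1.48e-132, across hotspots, which are not replicates). Long non-coding RNA genes were not counted as genes here, so such a summit may lie in one of them. Coding exons held 65 summits (10.4%) against 58.8% of probes.

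Some long-studied loci stood far above the array median in WT. The ade6 gene of purine synthesis (chromosome III, 1316281 to 1318035) read 7.20 over its 9 probes; its allele in these strains is not given in the sources used here. The rec12 gene, which carries the tag (chromosome I, 1772925 to 1774203), read 5.50 with its flanks. A probe inside the gene, picked for its low input, had at most 0.797% of the array's median input on each of the 5 arrays. The mating-type region (chromosome II, 2114219 to 2133394) had a median of 4.01 over 54 probes, all of them inside hotspots. Intergenic regions of at least 3 kb had a median of 3.36 and shorter ones 1.19, against −0.44 for coding exons. Probes within 50 kb of the largest central gap in each chromosome's probes, taken as pericentromeres, had a median of −0.77 compared with 0.01 on the arms. Subtelomeres of 100 kb had 0.17, a sign that turned to −0.10 with 50 kb. The WT count rests on 1 array and on its scale: quantile normalisation across arrays left 285 hotspots, and calling on the mean of the 4 genotypes left 235.

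Whether breaks at these hotspots need the cohesin Rec8 was asked by comparing the rec8Δ-labelled arrays with WT. Nearly the whole set fell: 689 of 714 hotspots were lower (limma, Benjamini-Hochberg adjusted) and 0 were higher, also at an unadjusted p under 0.05. The hotspots were called on the same single WT array, which by itself favours lower values on any other array. The median difference was −1.99, a 3.96-fold drop, and the median hotspot level was 0.00 and 0.06 on the replicates against 2.01 in WT. The mating-type region went from 4.01 to −0.11 ± 0.03 (SD, n = 2) and ade6 from 7.20 to 0.94 ± 1.01 (SD, n = 2). Some hotspots kept part of their signal, with at least 2-fold at 6 on replicate 1 and 46 on replicate 2.

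The largest called decreases in the rec8Δ-labelled arrays included the following hotspots. Between wis1 and its neighbour the level fell by 4.70 (SE 0.189, limma adjusted p = 0.00464). Between rtn1 and its neighbour (chromosome II, 1262169 to 1271993) it went from 4.58 to −0.04 ± 0.06, between the phosphatase gene sds21 and mug111 (chromosome III, 622848 to 634800) from 4.25 to −0.06 ± 0.08, and between hel2 and nmt1, the thiamine-repressible gene (chromosome III, 1832708 to 1845087), from 4.41 to 0.30 ± 0.32. The hotspot between sul1 and spo14 (chromosome II, 1884212 to 1893200) went from 4.27 to 0.14 ± 0.17. The highest differences from WT, all still negative, were at short weak hotspots in nhe1 (−0.61, SE 0.354), ipk1 (−0.77, SE 0.167) and at SPBC21.03C (−0.79, SE 0.450). Of these ipk1 passed the test (limma adjusted p = 0.0278), but its difference turned positive with quantile normalisation.

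Signal of at least 2-fold remained at 6 hotspots on both rec8Δ-labelled arrays, 2 on chromosome I and 4 on II, and these were chosen after their values were seen. Between pcs2 and hsr1 the replicates read 2.01 and 3.54 (5.12 in WT; difference −2.35, SE 0.832, limma adjusted p = 0.0792). SPAC110.06 (chromosome I, 1903253 to 1908678) read 1.37 and 2.75 against 3.81. Between cyc3 and ste11 they read 1.26 and 2.55 (adjusted p = 0.0379), between rps1801 and mbx2 1.04 and 2.70, between ecl3 and pho84, a phosphate transporter gene (chromosome II, 4440185 to 4448563), 1.20 and 2.49, and between rgp1 and ssn6 (chromosome II, 3856567 to 3865017) 1.07 and 2.36. The replicates differed in scale, with 46 hotspots at least 2-fold on replicate 2 (23, 19 and 4 on chromosomes I, II and III) and 6 on replicate 1. By the hotspot rule, 135 regions were called on replicate 2 alone and 41 on replicate 1. Rec8 was at 1.47% in the IP of replicate 2 and 33.5% in that of replicate 1, so the count of 6 is set by the array whose IP goes against its label. Called on the mean of both arrays, 83 regions passed the hotspot rule, of which 82 overlapped WT hotspots. The other was the rec8 deletion itself (chromosome II, 2567579 to 2572158).

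**Figure D2:**
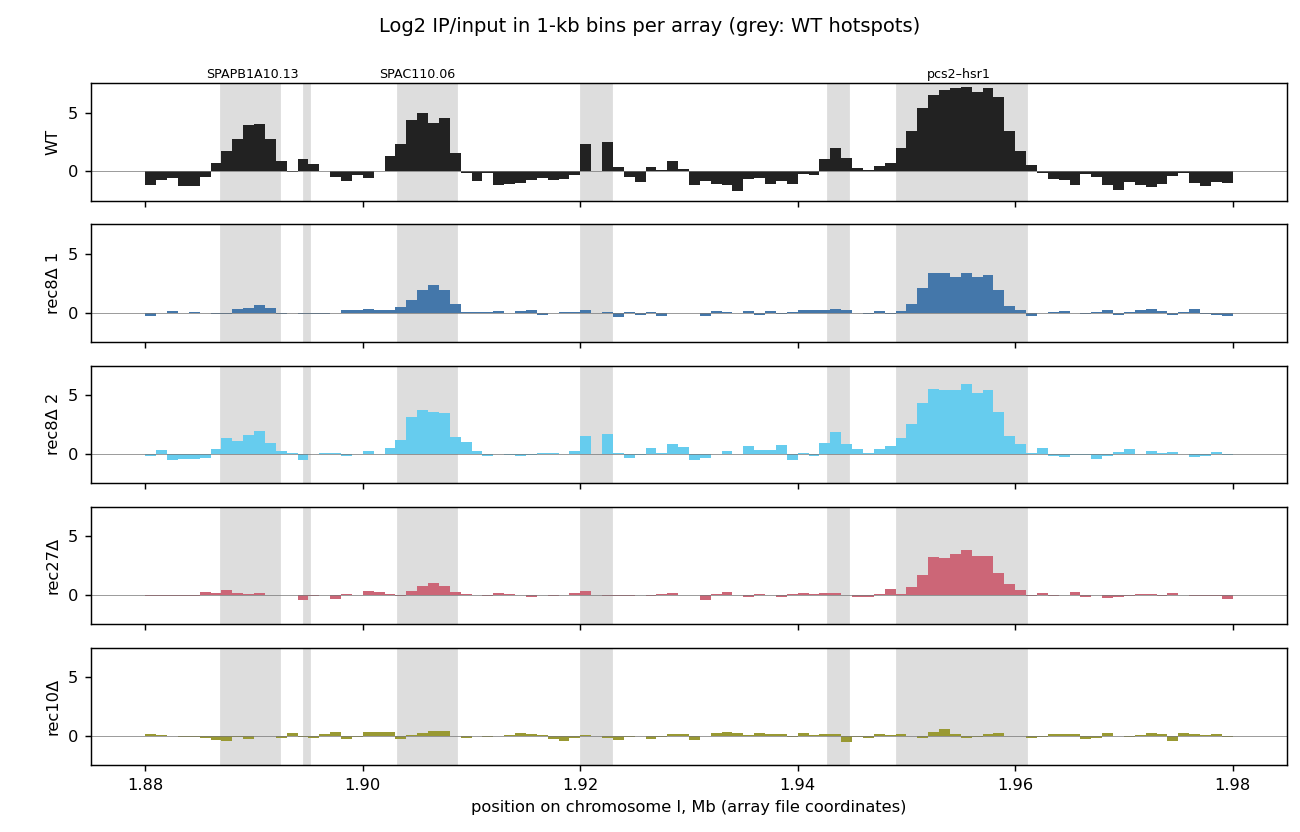
Log2 IP over input in 1-kb bins on the 5 arrays (1 panel each) along a stretch of chromosome I, positions in Mb of the array design, with WT hotspots in grey and 3 of them named. The hotspot between pcs2 and hsr1 stands out on WT, both rec8Δ-labelled arrays and the rec27Δ-labelled array, and on the rec10Δ-labelled array it averages 0.13.

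The same comparison was made for gene groups fixed in advance. Over all 4596 genes, 1724 fell and 1116 rose (limma, adjusted), or 2860 and 60 with centring on the mode and 2 and 1 with quantile normalisation. Values are means over the gene with its flanks, counts are of limma calls over all of these genes, and the second count is adjusted over the list alone. Glycolysis and fermentation genes had the highest WT median of the lists (3.69, above all 10000 random lists), and 9 of 12 measured members fell in the rec8Δ-labelled arrays (10 adjusted over the list alone). The dehydrogenase genes adh1 and tdh1 went from 4.38 and 4.39 to −0.37 ± 0.07 and 0.24 ± 0.29, and the enolase gene eno101 from 3.78 to 0.04 ± 0.09, while pfk1 stood at −0.49 in WT and −0.10 ± 0.06 in the rec8Δ-labelled arrays (limma adjusted p = 0.0935). Of the nitrogen-starvation genes, 7 of 9 fell (7 adjusted over the list alone), among them the ammonium transporter gene amt1 (3.65 to 0.02 ± 0.06) and the protease gene isp6 (4.26 to 0.61 ± 0.46). Of the stress genes, 10 of 15 fell (11 adjusted over the list alone). The small heat-shock gene hsp16 went from 6.20 to 1.31 ± 0.96 and the transcription factor gene atf1 from 2.08 to 0.01 ± 0.03, while the trehalase gene ntp1 read −0.17 and −0.09 ± 0.12 (adjusted p = 0.705). Membrane transporters fell at 13 of 17 members (15 adjusted over the list alone), and at fewer with loess. The iron transporter gene str1 went from 3.48 to 0.25 ± 0.01, whereas pho84, in a kept hotspot, went from 4.91 to 2.28 ± 1.07. Histone genes fell at 6 of 8 (6 adjusted over the list alone), and at fewer with loess. The H4 gene hhf2 went from 3.95 to −0.17 ± 0.02 and hhf3 from 5.47 to 2.12 ± 1.38.

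Genes of meiosis itself were mixed. Of the break-formation and axis genes, 4 of 15 fell and 7 rose (the same numbers adjusted over the list alone), with a median difference of 0.52 that turned to −0.26 when arrays were centred on the mode of their values. Members that fell were rec12 (−4.99, SE 0.358), its partner rec7 (4.08 to 0.13 ± 0.02), rec27 and rec15. Those that rose included the cohesin genes psm3 (−1.03 to −0.06 ± 0.02) and rec11 (−1.24 to −0.01 ± 0.10), which lie in regions below the WT median, and the deleted rec8. The rec8 difference (3.44) does not measure breaks, yet it is part of the count and median of this list. Of the repair genes, 7 of 14 fell (7 adjusted over the list alone) and 2 rose (3 adjusted over the list alone). The repair genes rad55 and rad57 fell by 2.99 (SE 0.202) and 2.97 (SE 0.260), and dmc1 read 0.06 in WT and 0.09 ± 0.28 in the rec8Δ-labelled arrays. Meiosis regulators split 5 lower and 4 higher of 13 (6 and 5 adjusted over the list alone), their median difference of −0.07 turning to 0.15 with a common input and to 0.31 over gene spans alone. In this list mei3, the inducer of meiosis, fell by 3.42 (SE 0.168), ste11 fell by 3.09 (SE 0.407) and mei4, a transcription factor gene, rose by 0.81 (SE 0.161). The mei4 level went from −0.79 to 0.02 ± 0.00, and the mode of the WT values lay at −0.79 relative to the WT median. This rise, and others of like size from below that median, therefore depend on the centre chosen. Of the pheromone genes, 7 of 14 fell (7 adjusted over the list alone), including the pheromone precursor gene mfm2 (4.42 to −0.14 ± 0.09) and the G-protein gene gpa1 (2.45 to 0.01 ± 0.00).

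Repeated families and the remaining lists were read in the same way. Of the wtf family, which includes meiotic drivers, 16 of 22 fell (20 adjusted over the list alone), wtf25 from 4.97 to 0.27 ± 0.21, and 4 of 7 Tf2 retrotransposons fell (4 adjusted over the list alone), each measured by 1 flanking probe. These families have near-identical copies, so DNA of other copies can hybridise to their probes. The tRNA genes counted 67 lower and 16 higher of 126 (67 and 16 adjusted over the list alone), and without flanks 2 of the 3 with a probe inside the gene were lower. Ribosomal protein genes counted 55 lower and 14 higher of 125 (53 and 12 adjusted over the list alone), and cell-surface genes 8 lower and 1 higher of 13 (8 and 1 adjusted over the list alone), with gas2 from 3.26 to 0.23 ± 0.05. Loess left fewer cell-surface genes lower. On rec8Δ-labelled replicate 2, which shared the slide of WT, the medians of the 14 lists lay between −0.14 and 0.35. The median difference over all genes was −0.13, and it was −0.90 with centring on the mode, so smaller differences than this depend on the centre chosen. With quantile normalisation limma called 0 members of any list lower (58 unadjusted). Against random lists of genes of like mean ratio, the median difference of the tRNA, glycolysis, nitrogen-starvation and ribosomal protein genes lay at percentiles 0.26, 2.78, 4.1 and 4.81, where low means a larger drop. The Tf2, wtf and break-formation lists lay at 99.55, 99.74 and 99.98, a smaller drop or a rise, and the other 7 lists lay between 15.16 and 88.34. The break-formation list lay at 99.51 in the rec27Δ-labelled array and at 74 in the rec10Δ-labelled array. It includes rec8, deleted in the rec8Δ-labelled arrays, and rec27, deleted in the rec27Δ-labelled array. The rec27 difference was 0.59 in the rec27Δ-labelled array, where almost no input is left. It was −1.36 in the rec8Δ-labelled arrays and −1.64 in the rec10Δ-labelled array. The percentiles of 99.98 and 99.51 therefore each include a ratio that does not measure breaks.

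Genome-wide, 3844 of 12011 bins of 1 kb fell and 2637 rose in the rec8Δ-labelled arrays (limma, adjusted p under the 0.05 threshold), where bins that fell had a WT median of 2.17 and those that rose −1.14. Centring on the mode moved that split to 5953 lower and 207 higher. Within slide 1 the median hotspot difference was −1.95, with 673 hotspots lower by at least 2-fold, and a slide block gave the same −1.95 without a test. The WT input was itself lower at hotspots (−0.85 against −0.13 on the 4 mutant-labelled arrays, log2 inside minus outside), and with a common input the median difference was −1.83. Under quantile normalisation it was −0.93, 143 hotspots were lower and 11 higher, and the level between cyc3 and ste11 was above WT by 0.26. The correlation of change between neighbouring hotspots was r = −0.04 (permutation p = 0.817, adjusted 0.908 over 3 comparisons). The call turned with the setting: r was 0.13 when hotspots were called and measured on different probes (adjusted permutation p = 0.00219), and 0.52 and 0.61 with hotspots defined on the mean of 4 genotypes and with quantile normalisation (adjusted permutation p = 1.5e-05 for both).

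Whether the linear element protein Rec27 is needed was asked in the same way. The IP of the rec27Δ-labelled array held rec27 at 70.9% of the expected level, so a drop there cannot be assigned to the deletion alone. In the rec27Δ-labelled array 691 of 714 hotspots were lower than WT and 0 were higher (limma, adjusted; 693 and 0 unadjusted), with a median difference of −2.09, a 4.25-fold drop. The mating-type region went from 4.01 to 0.42, ade6 from 7.20 to 0.45 and rec12 from 5.50 to 0.02. The hotspots between pcs2 and hsr1, ecl3 and pho84, and cyc3 and ste11 kept levels of 2.08, 1.78 and 1.68.

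The largest called decreases in the rec27Δ-labelled array included the hotspots between wis1 and its neighbour (−4.79, limma adjusted p = 0.00631), beside txc1 (−4.40, adjusted p = 0.00755), beside pmp3 (chromosome II, 886218 to 895660; 4.58 to 0.16), between sds21 and mug111 (4.25 to −0.14), and at 4429007 to 4434839 on chromosome I (4.97 to 0.25). The highest differences were at cym1 (−0.72), where the hotspot (chromosome II, 754082 to 757952) takes in part of the deleted rec27 and its ratio is raised by the missing input, at oca8 (−0.75, or 0.88 with loess) and between dao1 and wtf16 (−0.94). All of these turned positive with quantile normalisation. At least 2-fold signal remained at 4 hotspots, 1 on chromosome I and 3 on II. All 41 regions called on this array overlapped WT hotspots. The deleted rec27 lies partly inside the WT hotspot at cym1, so a region called at the deletion would count as overlapping without measuring breaks.

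Glycolysis genes fell at 9 of 12 members in the rec27Δ-labelled array (9 adjusted over the list alone), nitrogen-starvation genes at 7 of 9 (8 adjusted over the list alone), stress genes at 10 of 15 (10 adjusted over the list alone), membrane transporters at 13 of 17 (14 adjusted over the list alone), the wtf family at 16 of 22 (16 adjusted over the list alone) and tRNA genes at 66 of 126 (66 adjusted over the list alone). Examples were adh1 (−4.53, adjusted p = 0.000607 by limma), hsp16 (−5.51), amt1 (−3.59) and wtf25 (−4.93), and pho84 fell by 2.70 to 2.22. Break-formation and axis genes counted 3 lower and 5 higher of 15 (3 and 5 adjusted over the list alone), with rec7 at −3.77 and rec11 at 1.31. This list includes the deleted rec27, which read 2.13 against 1.54 in WT, a ratio raised by the missing input that does not measure breaks. Over all 4596 genes, 1617 fell and 914 rose by limma, or 2709 and 33 with centring on the mode and 0 and 1 with quantile normalisation (497 and 223 unadjusted). By bins, 3580 fell and 2045 rose, or 5510 and 114 with centring on the mode. WT and the rec27Δ-labelled array lay on different slides, and the slide block gave a median hotspot difference of −1.99 without a test. With quantile normalisation the median was −1.14, 160 hotspots were lower and 5 higher, limma called 0 list members lower (69 unadjusted), and the levels between cyc3 and ste11 and between rps1801 and mbx2 exceeded WT by 0.67 and 0.36.

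For Rec10, another linear element protein, the same comparison left almost no hotspot signal. The IP of the rec10Δ-labelled array held rec10 at 81.5% of the expected level, so the low signal cannot be assigned to the deletion alone. In the rec10Δ-labelled array 693 of 714 hotspots were lower than WT and 0 were higher (limma, adjusted; 694 and 0 unadjusted), with a median difference of −2.04, a 4.12-fold drop. At least 2-fold signal was seen at 0 of 714 hotspots. This array lay on slide 2, where rec8Δ-labelled replicate 1 had 6 such hotspots and the rec27Δ-labelled array 4. The rec8Δ-labelled array on slide 1 had 46, and slide and genotype are not separated in a comparison with it. The mating-type region read 0.14, ade6 −0.07, rec12 0.07, and the hotspot between pcs2 and hsr1 0.13. The highest of the 10 strongest was the hotspot between cyc3 and ste11, at 0.61.

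The largest called decreases in the rec10Δ-labelled array included those at 3981925 to 3989886 on chromosome I (5.14 to 0.01, limma adjusted p = 0.0121), at 4429007 to 4434839 (−5.04), between pcs2 and hsr1 (−4.99, adjusted p = 0.0216), between wis1 and its neighbour (−4.86), between rps1801 and mbx2 (−4.70) and at puf5 (chromosome I, 757579 to 769686; −4.62). The highest differences were at weak hotspots, between aar2 and pkl1 (−0.78), at rpl3202 (−0.80) and at sod22 (−0.80, or 0.54 with loess). All of these turned positive with quantile normalisation. The hotspot rule called 2 regions on this array. One was the rec10 deletion itself (chromosome I, 4295062 to 4297739), and the other overlapped a WT hotspot.

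Glycolysis genes fell at 9 of 12 members in the rec10Δ-labelled array (9 adjusted over the list alone), with a median difference of −4.14, nitrogen-starvation genes at 7 of 9 (8 adjusted over the list alone), stress genes at 10 of 15 (10 adjusted over the list alone), membrane transporters at 13 of 17 (13 adjusted over the list alone) and the wtf family at 16 of 22 (16 adjusted over the list alone). Break-formation and axis genes counted 4 lower and 5 higher (4 and 5 adjusted over the list alone), meiosis regulators 5 and 4 (5 and 4 adjusted over the list alone) and repair genes 7 and 3 (7 and 3 adjusted over the list alone). Over all 4596 genes, 1623 fell and 967 rose, or 2736 and 27 with centring on the mode and 27 and 1 with quantile normalisation. The pho84 and ste11 genes read 0.31 and 0.41, with differences from WT of −4.61 and −3.95 (limma adjusted p = 0.00717 and 0.00334). Bins counted 3574 lower and 2053 higher, or 5551 and 103 with centring on the mode. The slide block gave a median hotspot difference of −2.01 without a test, and quantile normalisation −1.27 with 203 hotspots and 1 list member lower.

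**Figure D3:**
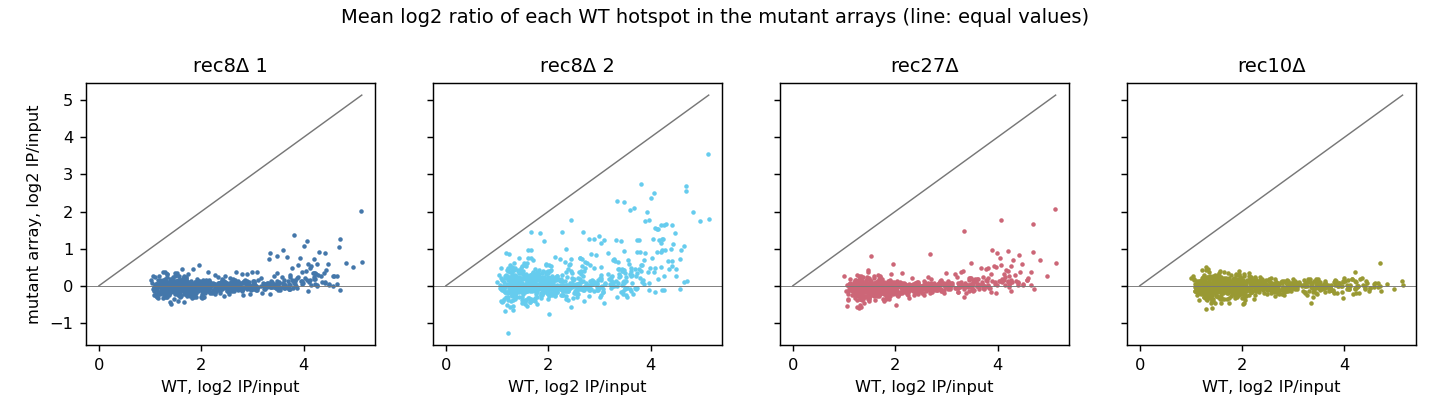
Mean log2 IP over input of the 714 WT hotspots on each mutant-labelled array (vertical axis) against WT (horizontal axis), 1 point per hotspot, with lines of equal values and of 0. Most points lie far below the line of equality, and the highest are at 2.01, 3.54, 2.08 and 0.61 for rec8Δ-labelled replicates 1 and 2, the rec27Δ-labelled array and the rec10Δ-labelled array.

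The mutant-labelled arrays were also set against each other. Between the rec27Δ-labelled and rec8Δ-labelled arrays 0 of 714 hotspots and 0 of 12011 bins differed after limma's Benjamini-Hochberg adjustment, with 5 hotspots lower and 1 higher at an unadjusted p under 0.05, and 61 such bins. The higher hotspot was the one at cym1 (0.81), which takes in part of the deleted rec27 and is raised by the missing input. A p that misses the threshold does not show equal levels. The median hotspot difference was −0.08, and within slide 2 it was −0.02 against rec8Δ-labelled replicate 1. At SPAC110.06 the rec27Δ-labelled array read 0.47 and the rec8Δ-labelled arrays 1.37 and 2.75, whereas between ecl3 and pho84 the values were 1.78 against 1.20 and 2.49. Over hotspots the rec27Δ-labelled array correlated with rec8Δ-labelled replicates 1 and 2 at Pearson r = 0.73 and 0.67 (Spearman 0.49 and 0.40). The rec8Δ-labelled arrays correlated with each other at 0.79 (Spearman 0.49). WT correlated over hotspots with the rec27Δ-labelled array at Pearson r = 0.45, with rec8Δ-labelled replicates 1 and 2 at 0.44 and 0.49, and with the rec10Δ-labelled array at 0.06. Over bins, WT correlated with rec8Δ-labelled replicate 2 at Pearson r = 0.50 (Spearman 0.24), with replicate 1 at 0.34 (0.11), with the rec27Δ-labelled array at 0.29 (0.05) and with the rec10Δ-labelled array at 0.04 (0.03). These correlations are across positions of the same arrays, which are not independent replicates.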

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

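The tests on the DNA found in the IP, and those on a shared slide and on carry-over, were chosen only after the result was seen.

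Signals outside the comparisons were measured at the deleted genes and on the mitochondrial genome. IP signal at the deleted gene was 81.5% of expected for rec10 on the rec10Δ-labelled array, 70.9% for rec27 on the rec27Δ-labelled array, and 33.5% and 1.47% for rec8 on rec8Δ-labelled replicates 1 and 2. The 66 mitochondrial probes had a median log2 IP over input of 1.11 on the rec27Δ-labelled array, 1.08 and 0.38 on rec8Δ-labelled replicates 1 and 2 and 0.48 on the rec10Δ-labelled array, all above −0.55 in WT. No explanation of the mitochondrial values was tested.

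The deleted gene was present in the IP of its own deletion array on slide 2. A signal floor of the IP channel is argued against, because the probe inside rec12 that is missing from all inputs read −7.14 ± 0.61 relative to the deleted genes in those IPs (log2, mean and SD over 3 arrays). Exchange of the whole IP with 1 other strain is argued against by rec8, at 44.2% ± 11 over the same arrays, between 1.47% in the IP of rec8Δ-labelled replicate 2 and 72.6% in that of WT, although the 55.4% of the rec27Δ-labelled array alone is nearer to WT. Mixing of DNA from other strains of the series into the IP remains a candidate explanation: rec8 was among the most depleted stretches of IP over input in the rec27Δ-labelled and rec10Δ-labelled arrays, at a percentile of at most 0.0141. But their spread is narrow, and the log2 ratio of −0.67 on the rec27Δ-labelled array is close to the −0.57 (percentile 30.9) of WT. The rec10Δ-labelled array read lower, at −1.15. The other deleted genes were less depleted on the slide 2 arrays of strains that carry them. There rec27 (2 probes) lay at percentile 3.67 on rec8Δ-labelled replicate 1 and 15.5 on the rec10Δ-labelled array. The rec10 run lay at 27.1 on rec8Δ-labelled replicate 1 and 41.1 on the rec27Δ-labelled array. The values that go with mixing are therefore those of rec8, and mixing of rec27Δ or rec10Δ DNA into these IPs was not seen in this way. No biological explanation was tested.

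Input signal on the WT array was lower at hotspots than elsewhere. A property of the probes there is argued against as the whole cause, since the dip averaged −0.13 on the 4 mutant-labelled arrays and −0.85 on WT. Interference from the bright IP dye in the same spot stays open: at an IP level of 3 to 4, rec8Δ-labelled replicate 2 had a median dip of −0.43 (SE 0.051) and WT −1.09, so a dip was there but smaller. Fewer intact copies near breaks in the WT strain is a biological alternative that was not tested.

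Hotspots between pcs2 and hsr1, ecl3 and pho84, and cyc3 and ste11 kept signal in both the rec27Δ-labelled and rec8Δ-labelled arrays. A residual of WT strength alone is argued against, as the arrays correlated over hotspots with WT held fixed (partial r = 0.61), and so is the shared slide, by r = 0.67 with rec8Δ-labelled replicate 2, on the other slide. Carry-over of rec8Δ DNA into the slide 2 IPs cannot be told apart from kept breaks, because its predicted size depends on the array taken as its source. The prediction took all rec8 missing from an IP as carried over, 56.3% for the rec10Δ-labelled array and 44.6% for the rec27Δ-labelled array. The IP of WT also fell short of rec8, at 72.6%, so this share may be too large. Predicted from replicate 1, whose own IP is mixed, the rec10Δ-labelled array lay below by a median of −0.67 (SD 0.36, range −1.31 to −0.23 over 6 hotspots), while the rec27Δ-labelled array lay above at 5 (0.31 to 1.12) and below at 1 (−0.31). Predicted from replicate 2, the rec10Δ-labelled array lay at −2.68 to −1.29, which argues against carry-over of that size there. The rec27Δ-labelled array lay at −1.36 to 0.17, a level carry-over of that size could bring. Smaller shares were not tested.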

How the results depend on the processing

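The tests with a common input, and those of the gene lists under normexp, loess, quantile normalisation and centring on the mode, were chosen only after the result was seen. Where a value moved or turned, the cause was not tested.

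The drop at hotspots kept its direction in all 3 mutant-labelled comparisons under every alternative run. In each, hotspots were called on WT or on a mean that includes WT, which by itself favours this direction. Quantile normalisation, which gives all arrays 1 distribution, made the drop smallest. It left 285 WT hotspots, of which 143, 160 and 203 were lower in the rec8Δ-labelled, rec27Δ-labelled and rec10Δ-labelled arrays, 11 were higher in the rec8Δ-labelled arrays and 5 in the rec27Δ-labelled array, and the median differences were −0.93, −1.14 and −1.27. Defining hotspots on the mean of 4 genotypes made it largest and left 235, of which 220, 227 and 234 were lower, with medians of −4.29, −4.67 and −4.86. In the same order the medians were −2.98, −3.11 and −3.13 with a 4-fold threshold, −2.15, −2.26 and −2.21 with at least 5 probes, −2.41, −2.56 and −2.54 when called on odd and measured on even probes, −1.88, −1.96 and −1.94 with loess, and −1.83, −1.89 and −1.83 with a common input. Centring on the mode gave −2.01 for the rec27Δ-labelled array and −2.00 for the rec10Δ-labelled array, normexp −2.03 for the rec27Δ-labelled array, and the slide block −1.99 for the rec27Δ-labelled array. Leaving out each rec8Δ-labelled array gave −2.05 to −1.95.

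Counts of 1-kb bins depended on the centre and the scale. With quantile normalisation 183, 182 and 431 bins were lower and 37, 59 and 225 higher in the rec8Δ-labelled arrays, the rec27Δ-labelled array and the rec10Δ-labelled array, while 17 bins were lower and 10 higher in the rec27Δ-labelled array than in the rec8Δ-labelled arrays. Centring on the mode gave 5953, 5510 and 5551 lower and 207, 114 and 103 higher, with 1 bin lower in the rec27Δ-labelled array than in the rec8Δ-labelled arrays. Bins higher in the rec27Δ-labelled array and the rec10Δ-labelled array numbered 1300 and 1337 with loess, 1110 and 1152 with a common input and 3185 and 3150 with a trend in eBayes, under which 5 bins were lower and 1 higher in the rec27Δ-labelled array than in the rec8Δ-labelled arrays. With 2-kb bins 2142, 2019 and 2035 were lower and 1667 were higher in the rec8Δ-labelled arrays, out of fewer bins. Profile correlation between the rec8Δ-labelled arrays was 0.563 with quantile normalisation, 0.746 in 2-kb bins and 0.595 with a common input, and that of the rec27Δ-labelled array with the rec8Δ-labelled mean was 0.710 in 2-kb bins and 0.514 with a common input.

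The correlation of change between neighbouring hotspots turned positive under several alternatives. For the rec8Δ-labelled arrays it was 0.614 with quantile normalisation, 0.524 with hotspots defined on the mean of 4 genotypes, 0.133 on odd and even probes, 0.022 with a 4-fold threshold, 0.020 with a common input, 0.016 with normexp and 0.0050 with at least 5 probes, and −0.04 to −0.00057 when each rec8Δ-labelled array was left out. For the rec27Δ-labelled array the values were 0.430, 0.328 and 0.106 for the first 3 of these and 0.0025 with a common input, and for the rec10Δ-labelled array 0.0488, 0.106 and 0.127 for the first 3. Adjusted permutation p for these first 3 was 1.5e-05, 1.5e-05 and 0.00219 in the rec8Δ-labelled arrays, 1.5e-05, 1.5e-05 and 0.00605 in the rec27Δ-labelled array, and 0.166, 0.0367 and 0.00261 in the rec10Δ-labelled array, and over all alternatives that kept both rec8Δ-labelled arrays it reached 0.924, 0.942 and 0.942.

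In the gene lists, quantile normalisation left 0 members lower in the rec8Δ-labelled arrays in each of the 14 lists by limma (58 members over all lists unadjusted), and 0 and 1 in the rec27Δ-labelled array and the rec10Δ-labelled array (69 and 65 unadjusted). Loess left 3 histone, 5 cell-surface and 6 membrane-transport genes lower. Centring on the mode gave 7 break-formation and axis genes, 12 pheromone genes, 98 ribosomal protein genes and 7 Tf2 elements lower, and a median for break-formation and axis genes of −0.26. The meiosis regulators had a median of 0.15 with a common input and 0.31 over gene spans alone, and over gene spans alone 2 of the 3 tRNA genes with a probe were lower. Subtelomeres of 50 kb had a WT median of −0.10.

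Among 29 named hotspots, 14 of 385 values under 7 alternatives turned direction. With loess these were sod22 in the rec10Δ-labelled array (0.54) and oca8 in the rec27Δ-labelled array (0.88). With quantile normalisation, the hotspot between cyc3 and ste11 read 0.26, 0.67 and 0.14 above WT in the rec8Δ-labelled arrays, the rec27Δ-labelled array and the rec10Δ-labelled array. Also above WT were rpl3202 (1.05), the hotspot between aar2 and pkl1 (0.49) and sod22 (1.19) in the rec10Δ-labelled array, the hotspot at 4778370 to 4786885 on chromosome I (0.013) and ipk1 (0.62) in the rec8Δ-labelled arrays, and cym1 (0.89), the hotspot between rps1801 and mbx2 (0.36), oca8 (0.47) and the hotspot between dao1 and wtf16 (0.18) in the rec27Δ-labelled array.

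Leaving out dim probes moved 0 of the 25 results that answer a comparison, and so did the deposited log10 table, which moved 2 of 55 values at named hotspots. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The slide block and leaving out a rec8Δ-labelled array leave 0 residual degrees of freedom, so they gave hotspot differences without a limma test and no counts. The neighbour correlation, tested by permutation, had p = 0.463 and 0.864 without replicates 1 and 2. No comparison had at least 3 arrays in each group, so other splits of the arrays were not counted. The lowest median IP brightness was that of WT, 8387 over a background of 128, and the filter on dim probes removed 3.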

Other observations

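The tests of neighbouring hotspot levels were chosen only after the result was seen.

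WT hotspots were separated by a median gap of 7.97 kb, or 9.01, 7.57 and 6.46 kb on chromosomes I, II and III. The longest stretches without a hotspot were 98.3 kb on chromosome I (3306043 to 3404310), 89.8 kb on II (1794373 to 1884212) and 109 kb on III (1048432 to 1157049), the last with no probes from 1098896 to 1140819. WT probe medians were −0.13, −0.02 and 0.33 on chromosomes I, II and III.

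Intergenic WT signal increased with the length of the gap between genes, with medians of 0.36, 0.94, 1.75, 3.15 and 3.36 for gaps of 0 to 0.5, 0.5 to 1, 1 to 2, 2 to 3 and at least 3 kb. Long non-coding RNA genes were not counted in setting these gaps. In gaps of at least 2 kb, divergent genes had a median of 3.40, tandem genes 3.15 and convergent genes 2.28, the last over 59 probes, of which 71.2% lay in hotspots against 70.2% for tandem genes. In gaps under 1 kb the order differed, with 0.81 for convergent, 0.61 for divergent and 0.58 for tandem genes.

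Levels of neighbouring hotspots correlated on rec8Δ-labelled replicate 2 (r = 0.26, permutation p = 1e-05, the smallest that 100000 permutations can give, one-sided), and less on rec8Δ-labelled replicate 1 (r = 0.07, permutation p = 0.0582). On the WT, rec27Δ-labelled and rec10Δ-labelled arrays r was −0.06, 0.02 and −0.02. Hotspots are not independent replicates.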
